A study of Homo sapiens with 4 samples.

How the data were processed

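RNA was extracted from A673 cells 48 h after transfection with siRNA, and ribosome-depleted total RNA libraries were sequenced as paired ends, per the labels' protocols. The labels give the tissue as muscle and the cell type as Ewing sarcoma. The submitters' processing notes name bcl2fastq, TopHat2, SAMtools and HTSeq and the genome build hg19, with no versions. The annotation, the strand setting, the counting mode and the treatment of duplicate reads are not given in the sources used here. The deposited files hold raw read counts per gene symbol, 1 file per library, as whole numbers with no normalization by the authors.

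Each file lists 23228 gene symbols and 5 HTSeq summary lines, which were left out of library sizes and ratios. Those lines held 44.8% of the entries in control_SMPD1, 44.1% in siSMPD1, 37.6% in control_GPR64 and 36.5% in siGPR64. Entries not uniquely aligned made up 30.1%, 29.1%, 21.4% and 20.1% in the same order, and entries outside annotated genes 14.1%, 14.4%, 15.5% and 15.7%. Reads that align to several places are thus absent from the gene counts, which lowers the counts of genes with near-identical copies such as histone, ribosomal protein and HSP70 genes. The share over whole libraries differed between the pairs, and the loss for these genes was not measured. Without a stated strand setting, reads of a gene and of an antisense partner cannot be told apart. The 10 genes with most counts held 2.82% to 3.4% of each library. Of the symbols, 19550 matched a current RefSeq symbol, 2386 matched a synonym alone and 1292 matched neither, and symbols are printed as the files give them. The reference annotation at hand is of another build, so no coordinates are given.

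Groups were taken from the labels: control_SMPD1, siSMPD1, control_GPR64 and siGPR64, with 1 library each. The titles pair each knockdown with a control. Whether the pairs were cultured and sequenced together is not given in the sources used here, and their depths differ. Gene count totals were 19614913 and 18849264 in the SMPD1 pair and 2882854 and 2534861 in the GPR64 pair. Counts were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3, computed over genes with at least 1 CPM in at least 1 library. The log2 ratio of a gene used a prior of 0.5 count, in proportion to library size. Its 95% interval is the exact Clopper-Pearson interval of the share of reads in the 2 libraries. It covers counting error only and holds no spread between cultures. Reads without molecular identifiers may not be independent molecules, so the interval may be too narrow even for counting error. Fold values are those log2 ratios as sizes. A gene with 0 counts in a library was set to 3 counts there and its ratio given as a lower bound. Of the list medians, that of interferon genes between the controls changed when such members were set to that bound.

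With 1 library per group, no group has a replicate of its own, so a rule of size was used: mean CPM of at least 1 over the 2 libraries, a ratio of at least 2-fold, and a counting interval that excludes equality. A gene shifted against both controls is past this rule against its paired control and at least 2-fold in the same direction against the other control, by the fitted ratio even where a library has 0 counts. For 34 gene lists with 1064 entries, the median log2 ratio of the members with a mean CPM of at least 1 was set against 10000 random lists of the same size, matched on expression in 20 bins. A list was taken as outside its random range below the 2.5 or above the 97.5 percentile. Random lists were drawn without regard to regulation, so this range does not allow for members that move together. Lists with fewer than 5 measured members have values alone, and none of the mitochondrially encoded genes was listed at a measurable level. The comparisons, lists, rule of size, named genes and most alternatives were fixed before the data were examined. Genes named are each target, the 10 higher and 10 lower genes whose interval bound lies furthest from 0 among those shifted against both controls, up to 4 members per list past the rule (otherwise up to 2 by size), 5 shared genes per direction, and PGF and MMP1. Other genes are marked as chosen after their values were seen. Not every gene the rule names is printed.

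The rule was tested on simulated counts that held counting error alone. In each comparison 200 genes were changed, drawn from genes with at least 5 CPM in the control. In each of the 3 comparisons 100% of genes changed 4-fold or 8-fold passed it. Of genes changed 2-fold, 50% passed for siSMPD1 over 12668 genes, 48% for siGPR64 over 12714 genes and 52% between the controls over 12693 genes. Unchanged genes passed in 8, 80 and 68 cases. Variation between cultures was not simulated, and the shares above do not hold for changed genes at lower levels. As alternatives, edgeR's quasi-likelihood test and DESeq2 1.42.0 were run on the counts with the 2 controls as replicates of a single group, which leaves 1 residual degree of freedom and puts the difference between the pairs into the spread. In a simulation of siSMPD1 against 2 controls over 13557 genes, edgeR called 0, 16, 42 and 50 of 50 genes changed 2-fold, 4-fold, 8-fold and 16-fold, and 8 unchanged genes, where DESeq2 called 2, 22, 41 and 49, and 20 unchanged genes. A model with terms for pair and knockdown, which also leaves 1 residual degree of freedom, was added after the data were examined. In a simulation over 13460 genes it called 10, 50, 50 and 50 of 50 genes by edgeR and 7, 47, 50 and 50 by DESeq2 at the same 4 sizes, with 7 and 2 unchanged genes. In the edgeR and DESeq2 simulations changed genes had a mean of at least 5 CPM, all genes had the same spread, and the pairs did not differ. For the model of pair and knockdown, a changed gene had the same fold in both knockdowns. The data differ in these respects, so the shares called need not hold for them. Other alternatives were DESeq2 size factors, total counts, filters of no and of 5 CPM, a prior of 5 counts, thresholds of 1.5-fold and 3-fold, the other control, and both controls pooled. Thinned libraries, counts of 0 set to 3 and ratios centred over GC content and transcript length were added after the data were examined. GC content and length came from the longest GENCODE 29 transcript of each symbol and were found for 92.4% of genes. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.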

Results

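Transcript levels were measured by total RNA sequencing in A673, an established Ewing sarcoma cell line that carries the EWS-FLI1 fusion. Cells received scrambled siRNA or siRNA against SMPD1 or GPR64 and were harvested 48 h later. SMPD1 encodes acid sphingomyelinase, the lysosomal enzyme that cuts sphingomyelin into ceramide and phosphocholine. GPR64, now named ADGRG2, encodes an adhesion G protein-coupled receptor. The 4 libraries form 4 groups of 1 library: siSMPD1 with its control (control_SMPD1) and siGPR64 with its control (control_GPR64). The deposited read counts over 23228 genes summed to 19614913 in control_SMPD1 and 18849264 in siSMPD1, but to 2882854 in control_GPR64 and 2534861 in siGPR64. A count of 0 thus allowed up to 0.15 and 0.16 CPM (scaled gene counts) in the SMPD1 pair and up to 1.04 and 1.18 CPM in the GPR64 pair. With 1 library per group no difference has a replicate check. Each ratio below compares 2 libraries, with a 95% interval that covers counting error only.

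The targeted genes were read first in every library. SMPD1 stood at 414 CPM in control_SMPD1 and at 91.7 CPM in siSMPD1, which is 4.52-fold lower (95% counting interval 4.29 to 4.76). GPR64 stood at 108.6 CPM in control_GPR64 and at 50.1 CPM in siGPR64, which is 2.16-fold lower (1.76 to 2.68). Both targets were thus lower in their own knockdown library than in its paired control. The levels in control_GPR64 differed from those in control_SMPD1 for both genes. SMPD1 was at 52.8 CPM in control_GPR64, below its level in siSMPD1, and at 232 CPM in siGPR64, which is 4.38-fold above its control (3.68 to 5.28). GPR64 was at 388 CPM in control_SMPD1 and at 539 CPM in siSMPD1, 1.39-fold higher (1.35 to 1.43) and under the 2-fold rule. Set against control_GPR64, the siSMPD1 library had a log2 ratio of 0.80 for SMPD1, so the direction of this target depends on which control is used. The direction of GPR64 in siGPR64 does not, with a log2 ratio of -2.95 against control_SMPD1.

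PGF, placental growth factor, a ligand of the receptor FLT1, was higher in both knockdown libraries: 3.07-fold in siSMPD1 (2.74 to 3.46) and 2.56-fold in siGPR64 (1.78 to 3.79). MMP1, an interstitial collagenase, stood at 2609 CPM in control_SMPD1, 2375 CPM in siSMPD1, 116.5 CPM in control_GPR64 and 689 CPM in siGPR64. It was 1.1-fold lower in siSMPD1 (1.08 to 1.11) and 5.91-fold higher in siGPR64 (5.26 to 6.66) than in the paired control. Against control_SMPD1 the siGPR64 library was lower for MMP1, with a log2 ratio of -1.92.

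**Figure D1:**
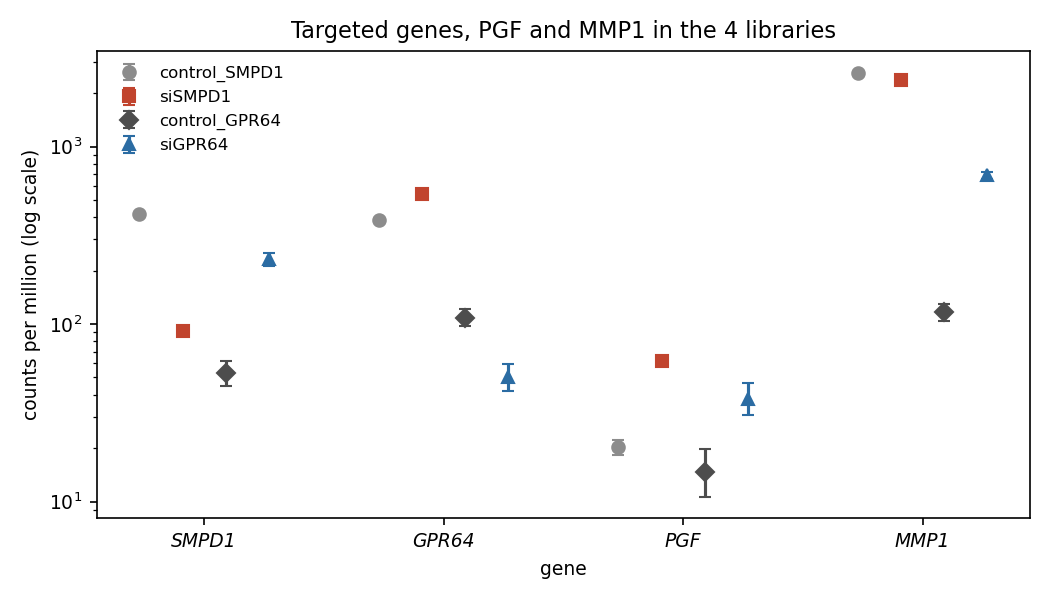
CPM on a log axis for SMPD1, GPR64, PGF and MMP1 in each of the 4 libraries, with bars for the 95% exact Poisson interval, which covers counting error only. SMPD1 is at 91.7 CPM in siSMPD1 and at 52.8 CPM in control_GPR64, and MMP1 is at 2609 CPM in control_SMPD1 and 116.5 CPM in control_GPR64.

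The first comparison asked which transcripts differ when SMPD1 is silenced. In the siSMPD1 library, targets of ATF4, the transcription factor of the integrated stress response that drives amino acid synthesis and transport genes, were lower as a group. ATF5 was 4.29-fold lower (4.12 to 4.47), and genes of the extracellular matrix and of lipid synthesis were higher as groups. Of 12749 genes with a mean of at least 1 CPM, 318 were higher and 141 lower by the rule of size, which is a ratio of at least 2-fold with a counting interval that excludes 1. These make up 3.6% of the measured genes. Of them, 175 higher and 81 lower genes also had a fitted ratio of at least 2-fold in the same direction against control_GPR64, and 34 had one in the opposite direction. With counts of 0 set to 3, these numbers were 161, 81 and 29.

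Among genes that differed against both controls, ISLR, which encodes a secreted leucine-rich repeat protein, was 8.62-fold higher (4.54 to 20.5), and COL2A1, a fibrillar collagen of cartilage, was 6.91-fold higher (4.05 to 13.5). FOXJ1, the master transcription factor of motile cilia, was 8.93-fold higher (3.58 to 38.2), and ZMYND10, a factor for assembly of ciliary dynein arms, was 9.83-fold higher (3.98 to 42.0). The carbonic anhydrase gene CA14 was 6.54-fold higher (3.49 to 14.9). RAB26, CSDC2, PLEKHD1 and ARSI were higher at 7.22-fold, 5.23-fold, 7.9-fold and 5.45-fold. Each of these genes had at most 5 counts in control_GPR64, with 1 for ZMYND10 and 0 for FOXJ1 and ARSI. Their ratios to that control thus rest on few reads, and no counting interval was required there.

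Among genes lower against both controls, the clearest after ATF5 was the non-coding RNA NCRNA00326, at 6.49-fold lower (3.64 to 13.5). CYR61, a matricellular protein and classical YAP target, was 4.46-fold lower (3.58 to 5.67). LAMP3, a lysosome-associated membrane protein, was 5.17-fold lower (3.03 to 9.91), and BTG3, an antiproliferative factor, was 3.22-fold lower (2.91 to 3.58). The phospholipase gene PLCG2 was 3.82-fold lower (2.61 to 5.89) and the mitochondrial carrier gene SLC25A24 2.83-fold lower (2.61 to 3.07). SLC35E1, PARP11 and MEST, the last an imprinted gene, were 3.12-fold, 3.75-fold and 3.15-fold lower.

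The ATF4-target list stood furthest from random lists in siSMPD1. Of its 34 measured members, 10 were lower, none higher and 24 short of the rule, and 8 of the 10 were also at least 2-fold lower against control_GPR64. The list's median log2 ratio was -0.79, where 95% of expression-matched random lists fell between -0.13 and 0.07. The list stood higher in control_GPR64 than in control_SMPD1, with a median of 0.76 between the controls. This alone favours lower ratios against control_GPR64, so the 8 members kept there are a weak check. Beside ATF5, the stress cytokine gene GDF15 was 2.8-fold lower (1.69 to 5.0), ALDH1L2, a mitochondrial folate enzyme, 2.57-fold lower (2.35 to 2.81) and VLDLR, a lipoprotein receptor, 2.51-fold lower (2.14 to 2.97). ALDH1L2 had a log2 ratio of 0.39 against control_GPR64. ATF4 mRNA itself had a log2 ratio of -0.36 in siSMPD1. The list of endoplasmic reticulum (ER) chaperones had a median of -0.13 inside its random range, with no member past the rule. Its members with the largest ratios were PDIA3 at 1.83-fold lower (1.76 to 1.9) and HYOU1 at 1.59-fold lower (1.54 to 1.63), and both had the opposite sign against control_GPR64, with log2 ratios of 0.07 and 0.20.

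Lipid and lysosome lists lay above their random ranges in siSMPD1 through many small ratios. The cholesterol synthesis list had a median log2 ratio of 0.31 (random range -0.15 to 0.06) with none of 26 members past the rule, and TM7SF2, a sterol reductase, was at 1.57-fold (1.45 to 1.7). The fatty acid synthesis list had a median of 0.24 (random range -0.20 to 0.12) over 13 members. PNPLA3, a lipid droplet acyltransferase and lipase, was its single member past the rule, at 2.9-fold higher (2.53 to 3.35). The lysosome list had a median of 0.17 (random range -0.11 to 0.09) with none of 47 members past the rule, and LAMP1 was at 1.93-fold (1.84 to 2.03). All 3 lists also lay above their random ranges against control_GPR64, which itself lay below control_SMPD1 for them, with medians of -0.34, -0.50 and -0.39. The sphingolipid list did not leave its random range, with a median of -0.00 over 39 members, and SMPD1 was its single member past the rule.

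Extracellular matrix and integrin genes had a median of 0.38 (random range -0.12 to 0.09), with 5 of 42 members higher and none lower. MMP2, a gelatinase, was 3.19-fold higher (2.95 to 3.47), the laminin gene LAMA5 2.89-fold (2.32 to 3.65), the proteoglycan gene VCAN 2.56-fold (1.31 to 5.62) and the integrin gene ITGA4 2.38-fold (1.7 to 3.41). BGN, named after its values were seen, was the fifth, with a log2 ratio of 1.22. Of these, MMP2 was also at least 2-fold higher against control_GPR64, where VCAN had 0 counts and so no firm ratio. LAMA5, ITGA4 and BGN were lower against that control, with log2 ratios of -0.43, -0.89 and -0.48. Adhesion receptor genes had a median of 0.35 (random range -0.18 to 0.21) with none of 16 past the rule, led by CELSR2 at 1.87-fold (1.77 to 1.98) and BAI2 at 1.7-fold (1.39 to 2.09).

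Inflammatory lists were lower in siSMPD1 against its paired control. The NF-kB and chemokine list had a median of -0.38 over 17 members (random range -0.18 to 0.31), and the neutrophil chemokine gene IL8 was 7.31-fold lower (4.03 to 15.8) and IL1B 2.87-fold lower (1.5 to 6.22). TRAF1, a signalling adaptor, was 2.67-fold higher (1.97 to 3.7). The interferon list had a median of -0.18 over 44 members (random range -0.10 to 0.14), with CXCL11 5.03-fold lower (2.45 to 13), CXCL10 2.9-fold lower (1.75 to 5.16) and GBP2 2.87-fold lower (2.26 to 3.7). IFITM2 was higher, at 2.56-fold (1.56 to 4.46). Neither list held against control_GPR64: the interferon median there was 0.91, CXCL10 and CXCL11 had 1 count and 0 counts in control_GPR64 and no determined direction, and the NF-kB median lay inside its random range. Cytosolic ribosomal protein genes had a median of -0.13 (random range -0.10 to 0.03) with none of 75 past the rule.

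Single genes passed the rule in lists that stayed inside their random ranges. Among immediate-early genes FOS was 2.42-fold lower (1.92 to 3.09), ATF3 2.14-fold lower (1.8 to 2.56) and EGR3 2.04-fold lower (1.17 to 3.78), while NR4A2 was 2.0-fold higher (1.06 to 4.07). In the YAP/TEAD list CTGF was lower alongside CYR61, at 2.59-fold (1.9 to 3.62). Among p53 targets, TP53INP1 was 2.48-fold higher (1.93 to 3.23), TP53I3 2.15-fold higher (1.46 to 3.28) and the cell cycle inhibitor gene CDKN1A 2.05-fold higher (1.86 to 2.27). CDKN1A was lower against control_GPR64, with a log2 ratio of -1.04. BMF, a BH3-only promoter of apoptosis, was 2.64-fold higher (2.42 to 2.88), and PMAIP1, another BH3-only gene, was 2.1-fold lower (1.96 to 2.25). The lactate exporter gene SLC16A3 was 2.7-fold higher (2.34 to 3.13) and ANKRD37 2.53-fold higher (1.56 to 4.36).

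Lists for the EWS-FLI1 programme, the cell cycle and energy metabolism did not leave their random ranges in siSMPD1. None of 34 EWS-FLI1-activated targets passed the rule, with a median of -0.04, and the values furthest from 0 belonged to GYG2 at 1.69-fold higher (1.58 to 1.81) and IGF1 at 1.55-fold lower (1.35 to 1.77). Medians were -0.01 for G1/S genes, -0.00 for G2/M genes, -0.05 for oxidative phosphorylation and -0.01 for autophagy, with no member of any of these past the rule. EWS-FLI1-repressed targets had a median of 0.06 (CDKN1A higher, CYR61 and CTGF lower) and invasion genes one of 0.18, with PGF as the single member of 10 past the rule. Neural genes had a median of -0.16, with MAP2 2.44-fold lower (1.34 to 4.87). Markers of skeletal muscle, immune and epithelial cells were mostly under 1 CPM, with 4, 2 and 3 measured members and none past the rule. Against control_GPR64, 12 lists lay above and 7 below their random ranges, among them hypoxia genes (median 0.63), EWS-FLI1-repressed targets (0.59), G1/S genes (0.27), immediate-early genes (-0.59), p53 targets (-0.54) and oxidative phosphorylation (-0.41). In the fibroblast and endothelial list the receptor gene KDR was 2.31-fold higher (1.28 to 4.53). In a model that took both controls as replicates of a single group, edgeR's quasi-likelihood test called no gene at an adjusted p under 0.05, with 179 genes at an unadjusted p under 0.05. DESeq2 called ATF5, at an adjusted p of 0.00206.

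The second comparison asked which transcripts differ when GPR64 is silenced. In the siGPR64 library ATF4 targets were again lower than in the paired control. Targets of NRF2 in the antioxidant response (5 of 25 members past the rule), heat shock genes (6 of 20) and measured histone genes (9 of 12) were higher as groups. Of 12830 measured genes, 842 were higher and 664 lower by the rule of size, or 11.7%. Against control_SMPD1, 617 of the higher and 379 of the lower genes lay within 2-fold in either direction, 71 were at least 2-fold the opposite way, and 196 higher and 243 lower genes kept a fitted 2-fold difference (196 and 203 with counts of 0 set to 3). Most genes past the rule in this pair thus depend on the control library used.

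Among genes that differed against both controls, CEND1, a neuronal cell cycle exit factor, had 0 counts in control_GPR64 and was at least 17.9-fold higher. OSGIN1, an oxidative stress response gene, also had 0 counts there and was at least 15.2-fold higher. FABP3, FAIM2 and the sodium channel gene SCN1A, likewise at 0 in the control, were at least 6.48-fold, 6.1-fold and 6.1-fold higher. HMOX1, the haem-degrading enzyme and a classical NRF2 target, was 8.57-fold higher (4.16 to 23.8), and MAP7D2, a microtubule-binding protein, was 9.44-fold higher (4.81 to 24.1). SLC4A8, a bicarbonate transporter, was 18.7-fold higher (6.09 to 200) and JPH2, a junctophilin, 16-fold higher (3.86 to 993), on 2 counts and 1 count in the control. HIST1H2BK was 4.63-fold higher (3.68 to 5.94).

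TXNIP, the thioredoxin-interacting protein whose transcription follows glucose supply, was 12.9-fold lower in siGPR64 (10.3 to 16.7). TXNIP stood higher in control_GPR64 than in control_SMPD1, so it was lower by a smaller factor against control_SMPD1 (levels under other observations). TRIB3, a pseudokinase induced by ATF4, was 6.29-fold lower (5.55 to 7.18), PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, 5.92-fold lower (4.79 to 7.45), and DDIT4, an inhibitor of mTORC1, 5.55-fold lower (4.49 to 6.97). INHBE, an activin subunit, was 9.54-fold lower (4.46 to 28.7). The epithelial cytokine gene TSLP was 14.0-fold lower (4.41 to 146) on 2 counts, and ZMAT1 16.4-fold lower (3.89 to 967) on 1 count. SP6 had 0 counts in siGPR64 and was at least 9.62-fold lower, with no determined direction against control_SMPD1. C6orf223 and the phosphatase gene PTP4A1 were 7.78-fold (4.68 to 14.7) and 4.72-fold lower (3.83 to 5.91).

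Of 34 measured ATF4 targets, 18 were lower in siGPR64, none higher and 16 short of the rule. The median log2 ratio was -1.20 (random range -0.16 to 0.16), and it was -0.52 against control_SMPD1, again below its random range of -0.20 to 0.16. Beside TRIB3, PCK2 and DDIT4, GDF15 was 11.6-fold lower (7.04 to 21.6), but its log2 ratio was 0.95 against control_SMPD1. The 5 members at least 2-fold lower against both controls were TRIB3, PCK2, DDIT4, VLDLR and SLC7A1, the last a cationic amino acid transporter chosen after its values were seen. ATF4 mRNA had a log2 ratio of -0.46 in this pair and 0.00 against control_SMPD1.

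NRF2 targets had a median of 0.59 (random range -0.20 to 0.21) and of 0.54 against control_SMPD1, above the random range in both. The 5 higher members of 25 were OSGIN1 and HMOX1, SRXN1 at 2.56-fold (1.88 to 3.55), the thioredoxin reductase gene TXNRD1 at 2.1-fold (1.93 to 2.29) and TALDO1, named after its values were seen. Heat shock genes had a median of 0.72 (random range -0.23 to 0.21), with 6 of 20 higher and none lower. HSPA8, the constitutive HSP70, was 5.2-fold higher (4.93 to 5.5), and the inducible HSPA1A 9.45-fold higher (6.01 to 16.5). HSPA1B was at 5.45-fold (3.82 to 8.19) and HSPA1L at 3.71-fold (1.11 to 23.4), and HSPA1A and HSPA1B are near-identical copies whose separate counts are uncertain. Against control_SMPD1 the heat shock median was 0.29, above the random range, and no member reached 2-fold there, with HSPA8 at a log2 ratio of 0.04.

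Of 32 replication-dependent histone genes, 12 reached 1 CPM, and 9 of these were higher in siGPR64 against both controls. The median log2 ratio was 1.95 (random range -0.50 to 0.58), and 3.27 against control_SMPD1, where control_GPR64 itself stood higher, with a median of 1.27 over 8 measured members. The members with the largest ratios had low counts: HIST1H2AG at 7.81-fold (1.63 to 496), HIST1H4H at 7.43-fold (2.15 to 82.0), HIST1H3H at 5.57-fold (1.03 to 361) and HIST1H2BJ at 5.16-fold (1.92 to 23.0). Histone genes have near-identical copies, so the split of reads between them is uncertain. G1/S genes had a median of 0.34 (random range -0.14 to 0.17), with 7 of 45 higher and none lower. CCNE2 and CCNE1, the E-type cyclins, were 8.98-fold (3.9 to 31.8) and 3.81-fold higher (1.98 to 8.57), UNG 3.24-fold (2.49 to 4.31) and E2F8 2.89-fold (1.85 to 4.74). The G1/S median was -0.00 against control_SMPD1, where E2F8 was lower with a log2 ratio of -0.54. G2/M genes had a median of -0.19 (random range -0.11 to 0.16) and of -0.17 against control_SMPD1, below the random range in both, with HMMR 2.1-fold (1.8 to 2.46) and NDC80 2.05-fold lower (1.75 to 2.42). HMMR had a log2 ratio of 0.36 against control_SMPD1.

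Genes linked to invasion had a median of 0.82 (random range -0.48 to 0.51), with 5 of 10 higher and none lower. Besides MMP1 and PGF these were MMP9 at 5.63-fold (1.53 to 63.1), the urokinase gene PLAU at 5.06-fold (2.05 to 18.4) and MMP10 at 4.01-fold (1.96 to 9.96). Against control_SMPD1 the list's median was -0.16, inside its random range, and PGF was the single member of these 5 that stayed higher, at a log2 ratio of 0.91. Extracellular matrix genes had a median of 0.45 (random range -0.18 to 0.19), with 8 of 40 higher and 3 lower. The fibrillin gene FBN1 was 4.84-fold higher (3.82 to 6.24) and ITGA1 4.08-fold higher (1.92 to 10.8), and FBN2 was 3.2-fold (2.35 to 4.48) and DCN 4.44-fold lower (1.17 to 48.3), where TIMP3, named after its values were seen, was the third lower member. This median was 0.13 against control_SMPD1, where ITGA1 and FBN2 pointed the opposite way with log2 ratios of -0.90 and 4.43. EWS-FLI1-repressed targets (median 0.43), YAP/TEAD targets (0.29) and fibroblast and endothelial markers (0.91) were above their random ranges against the paired control but not against control_SMPD1. Members past the rule were 3 higher and 3 lower, 5 higher and 2 lower, and 4 higher and 2 lower in these lists. Among the higher members NT5E, an ecto-nucleotidase, was 6.06-fold higher (3.78 to 10.7), PTRF 3.05-fold (2.21 to 4.32), FLT1 9.3-fold (2.03 to 587) and COL1A1 2.19-fold (1.72 to 2.82). Against control_SMPD1 NT5E and FLT1 had log2 ratios of -0.28 and -1.19.

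Neural genes had a median of 0.76 (random range -0.27 to 0.32), with 9 of 20 higher and 2 lower, and 0.14 against control_SMPD1. ELAVL3, a neuronal RNA-binding protein, was 4.72-fold higher (3.08 to 7.76), NEFL 3.53-fold (2.81 to 4.51) and the neurotrophin receptor gene NGFR 3.44-fold (2.91 to 4.11). CHGB was 7.47-fold lower (1.55 to 449) on 1 count, and SYP, named after its values were seen, was the other lower member. ELAVL3 and NGFR were also at least 2-fold higher against control_SMPD1. NEFL had a log2 ratio of -0.97 there. Lysosomal genes had a median of 0.43 (random range -0.17 to 0.19), with 8 of 48 higher, among them FLCN at 3.4-fold (2.65 to 4.45), GPNMB at 3.4-fold (1.15 to 15.6) and CTSZ at 11.5-fold (2.64 to 722). GAA, named after its values were seen, and MITF were lower, the latter at least 1.75-fold with 0 counts in siGPR64. The lysosome median was 0.01 against control_SMPD1. ER chaperones had a median of 0.27 (random range -0.22 to 0.22), with DERL3 and SDF2L1 at 7.81-fold (1.63 to 496) and 2.62-fold higher (1.87 to 3.77) and ERN1 and XBP1 at 2.54-fold (1.2 to 6.34) and 2.03-fold lower (1.74 to 2.36). Against control_SMPD1 the ER chaperone median was -0.43, below the random range.

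Targets of p53 had a median of -0.55 (random range -0.24 to 0.28), with 9 of 23 lower and none higher. A673 cells lack functional p53, and GDF15 and SESN2, 4.09-fold lower (3.34 to 5.08), are also members of the ATF4-target list. The death receptor gene TNFRSF10B was 3.7-fold lower (3.22 to 4.28) and CDKN1A 2.94-fold lower (2.38 to 3.67). The median was -0.12 against control_SMPD1, inside its random range. Interferon-stimulated genes had a median of 0.45 (random range -0.24 to 0.29), with 8 of 40 higher, among them the immunoproteasome gene PSMB8 at 5.93-fold (3.03 to 14.4) and IFIT3 at 3.24-fold (1.69 to 7.06). TAP1 was at 2.54-fold (1.37 to 5.12), and IFIH1 was 2.64-fold lower (1.06 to 8.47). Against control_SMPD1 the interferon median was -0.80, below the random range, and PSMB8, IFIT3 and TAP1 had log2 ratios of -0.94, -0.52 and -1.46. CDKN1A had one of 0.52.

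Ribosomal protein genes had a median of -0.21 (random range -0.11 to 0.09) with none of 76 members past the rule, and 0.38 against control_SMPD1, above the random range. The lists that follow stayed inside their random ranges against control_GPR64. Immediate-early genes had a median of -0.10, with EGR1 4.69-fold lower (4.07 to 5.44), ATF3 4.43-fold lower (3.26 to 6.24), KLF2 9.21-fold higher (3.3 to 54.9) and DUSP4 3.91-fold higher (2.48 to 6.63). The cholesterol median was 0.12, with TM7SF2 2.94-fold lower (2.16 to 4.11) and INSIG1 2.07-fold higher (1.78 to 2.42). The fatty acid median was -0.24, with ACLY, the enzyme that makes cytosolic acetyl-CoA, 2.47-fold lower (2.18 to 2.81). Against control_SMPD1 the cholesterol and fatty acid medians were -0.44 and -0.79, both below their random ranges, and INSIG1 and EGR1 pointed the opposite way with log2 ratios of -0.44 and 0.90. EWS-FLI1-activated targets had a median of 0.02, with CCK 9.26-fold lower (2.02 to 552) on 1 count, DKK2 2.39-fold lower (2.06 to 2.78) and KCNN1 2.24-fold higher (1.85 to 2.73). Medians were -0.06 for sphingolipid genes, 0.10 for hypoxia genes, -0.28 for NF-kB genes, -0.05 for apoptosis regulators, -0.09 for oxidative phosphorylation, -0.03 for autophagy, 0.25 for RNAi machinery and 0.30 for adhesion receptors. Past the rule were 4 adhesion receptors higher and 3 lower, with the siRNA target GPR64 itself among the lower. Also past it were 3 hypoxia genes higher and 4 lower, and 0 autophagy genes higher and 3 lower. Of these, GPR56 was 5.26-fold higher (2.15 to 19.1) among the adhesion receptors, ALDOC 2.63-fold lower (1.84 to 3.88) among hypoxia genes and NBR1 3.02-fold lower (2.39 to 3.87) among autophagy genes. Against control_SMPD1 immediate-early genes and oxidative phosphorylation lay above their random ranges, with medians of 0.46 and 0.32, and hypoxia genes below, with -0.33. Skeletal muscle, immune and epithelial markers had 4, 2 and 2 measured members. Of these PAX7, which Ewing sarcoma cells express, was 5.23-fold (4.05 to 6.91), CD68 2.47-fold (1.06 to 6.84) and KRT8 3.92-fold higher (2.34 to 7.18), with log2 ratios of -0.64, -0.53 and -0.13 against control_SMPD1, where the intervals of CD68 and KRT8 include 0. The model with both controls as replicates called no gene at an adjusted p under 0.05 by edgeR or DESeq2, with 313 and 211 genes at an unadjusted p under 0.05.

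**Figure D2:**
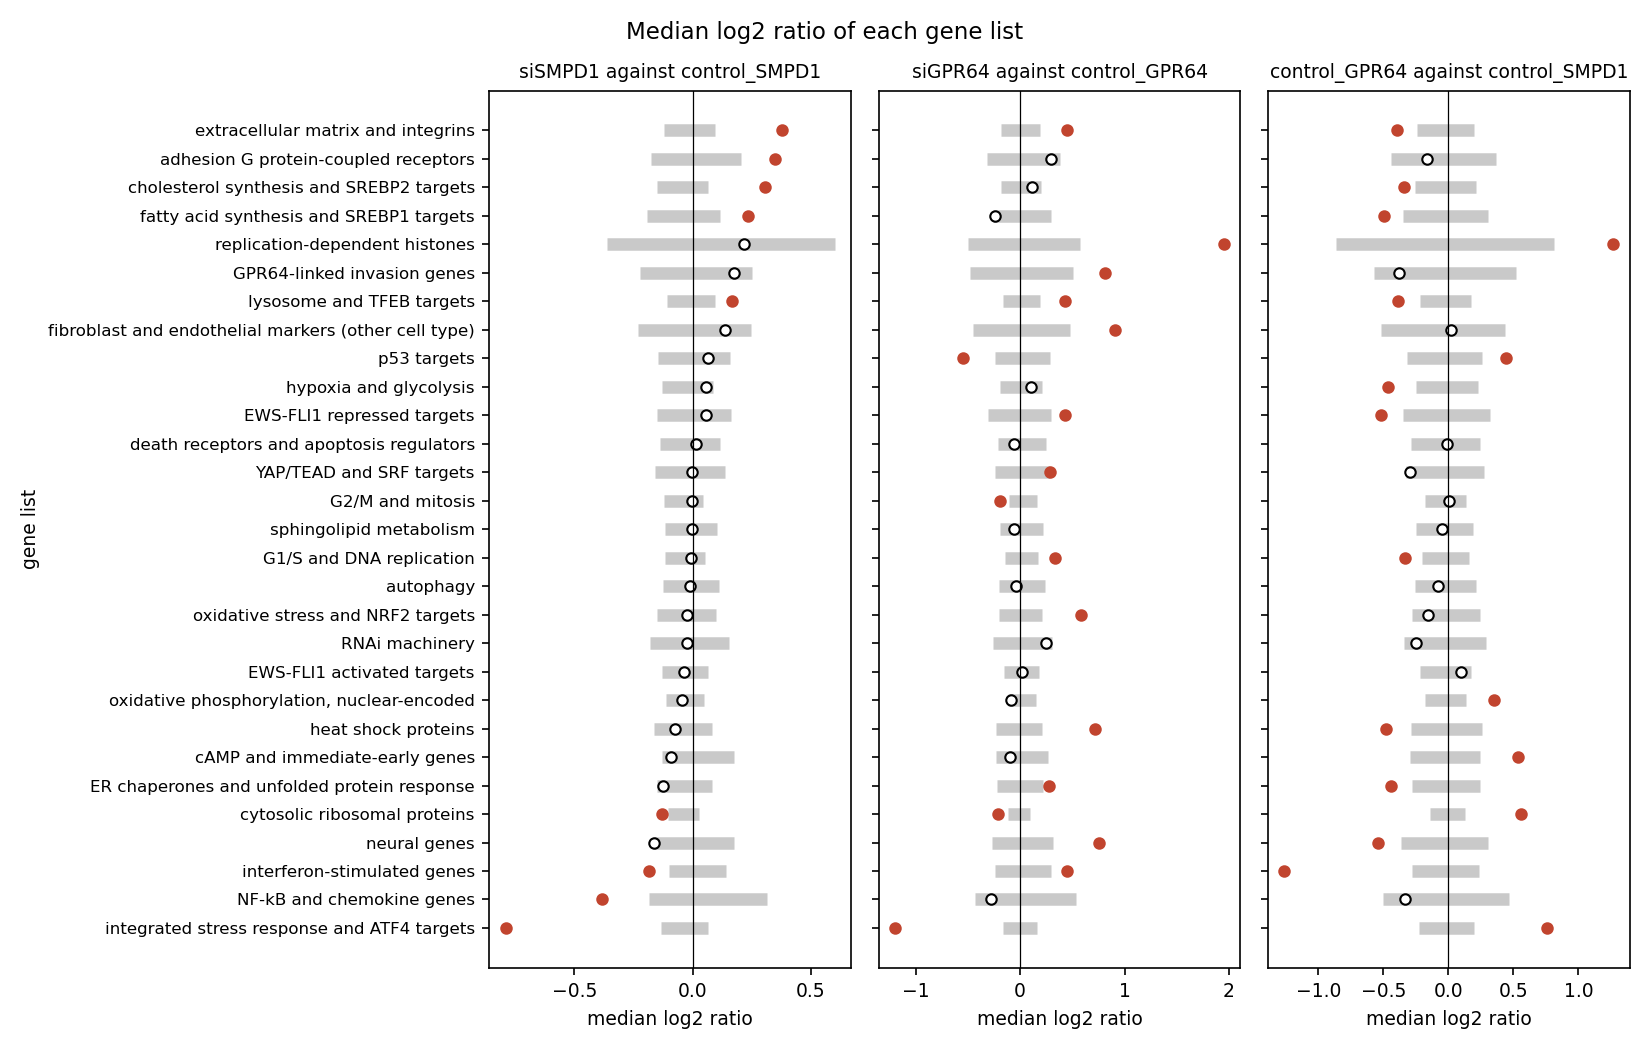
Median log2 ratio of 29 gene lists (x axis, log2 scale) in siSMPD1 against control_SMPD1, siGPR64 against control_GPR64 and control_GPR64 against control_SMPD1, with grey bars for the central 95% of expression-matched random lists and filled points for lists outside it. The ATF4-target list has medians of -0.79, -1.20 and 0.76 in the 3 panels, whose x axes have different scales.

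The 2 controls received the same kind of siRNA, and the 2-fold rule was also applied between them. They belong to different pairs, so their difference includes any difference between the 2 experiments and does not measure the spread within a pair. Of 12798 measured genes, 899 were higher and 1066 lower in control_GPR64 than in control_SMPD1, or 15.4%, a larger share than in either knockdown comparison. ATF4 targets had a median log2 ratio of 0.76 between the controls (12 of 34 higher, 1 lower, random range -0.22 to 0.20), and interferon-stimulated genes one of -1.26 (23 of 45 lower, none higher, random range -0.28 to 0.24). Ribosomal protein genes had a median of 0.56 (13 of 76 higher, random range -0.14 to 0.13), immediate-early genes of 0.54 (10 of 27 higher, 2 lower) and histone genes of 1.27 (5 of 8 higher, random range -0.86 to 0.82). Heat shock genes had a median of -0.48 (5 of 20 lower), hypoxia genes of -0.46 (10 of 35 lower, 1 higher), neural genes of -0.54, p53 targets of 0.44 and extracellular matrix genes of -0.39. With counts of 0 set to 3 the interferon median was -1.15. In all, 17 of 29 lists lay outside their random range between the controls, 6 above and 11 below. If the members of each list varied independently, 1.5 would be expected. Members regulated together can move together between any 2 cultures, so 1.5 is not the number expected for such lists. The corresponding numbers were 5 above and 4 below in siSMPD1 and 13 above and 4 below in siGPR64. Across genes, log2 CPM correlated at 0.986 between the libraries of the SMPD1 pair, 0.95 within the GPR64 pair and 0.941 between the controls. The siGPR64 library correlated at 0.957 with control_SMPD1 and 0.953 with siSMPD1, and control_GPR64 at 0.929 with siSMPD1, where genes are not independent replicates.

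The third question was whether the 2 knockdowns moved the same genes, each against its own control so that no library was shared. Of 12386 genes measured in both, 43 were higher in both, where independent lists of these sizes would share 17.1 and lists matched on expression 24.6. Another 43 were lower in both, against 6.2 and 8.3, and 32 went in opposite directions, against 21. Log2 ratios correlated weakly across genes, with Pearson's r of 0.135 and Spearman's rho of 0.11, and genes are not independent replicates. Of the shared genes, 16 higher and 14 lower had fitted ratios of at least 2-fold in the same direction against both controls in both knockdowns (16 and 12 with counts of 0 set to 3). ARNT2, a partner of bHLH-PAS transcription factors, was 6.96-fold higher in siSMPD1 (3.17 to 21.4) and 10.8-fold in siGPR64 (2.44 to 677). CEND1 and FAIM2 were 4.5-fold (2.86 to 7.64) and 5.26-fold higher (2.84 to 11.5) in siSMPD1, beside their lower bounds of 17.9-fold and 6.1-fold in siGPR64. FAM5B was higher in both, at 4.09-fold (2.72 to 6.51) and 5.57-fold (1.03 to 361), but was not among these 16. OPCML, a neural cell adhesion gene, was among them, at 3.88-fold (2.14 to 8.01) and 8.55-fold higher (1.83 to 541).

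Genes lower in both knockdowns included PTX3, a secreted pentraxin of innate immunity, at 9.02-fold lower in siSMPD1 (5.91 to 15.0) and at least 1.75-fold lower in siGPR64, where it had 0 counts. NCRNA00326 also had 0 counts in siGPR64 and was at least 1.75-fold lower there, and the protocadherin gene PCDH1 was 3.67-fold (1.8 to 9.04) and at least 3.5-fold lower. SULT1E1, the estrogen sulfotransferase, was 3.22-fold (2.47 to 4.28) and 3.48-fold lower (2.1 to 6.31), and TSLP was 2.95-fold lower in siSMPD1 (1.54 to 6.38). PTX3 and SULT1E1 were not among the 14 genes at least 2-fold lower against both controls in both knockdowns. NCRNA00326 and PCDH1 were among them by fitted ratio, but not with counts of 0 set to 3. Of the 34 ATF4 targets measured in both, 31 had log2 ratios below 0 in both knockdowns. A model of pair and knockdown over the 4 libraries, added after the data were seen, tested 1 effect shared by both knockdowns with 1 residual degree of freedom. That residual is the disagreement between the 2 knockdown ratios of a gene and holds no spread between replicate cultures. The calls thus favour genes whose 2 ratios are alike and give no replicate check of either knockdown. At an adjusted p under 0.05 edgeR called ATF5 (log2 ratio -1.83), TRIB3 (-1.96), PCK2 (-1.86) and CTH (-1.76) lower and the protocadherin gene DCHS1 (1.44) higher. The first 4 are ATF4 targets, and CTH, DCHS1 and DGKK are named after their values were seen. Of these ATF4 targets, TRIB3 and PCK2 were among the 14 genes lower against both controls in both knockdowns, and ATF5 and CTH were not. DESeq2 called 2 genes higher, DCHS1 and DGKK, and 9 lower, the 4 above included. With the controls exchanged between the knockdowns, 43 genes were higher in both, where independent lists would share 76.7 and lists matched on expression 113.4. Another 29 were lower in both, against 49.2 and 65.3, and 526 went in opposite directions, against 124.3. Both overlaps thus fell below the expected numbers, and Pearson's r was -0.395. Neither tool called a gene under that pairing. The model's effect hardly changes with the pairing, but the gap between the controls enters its spread. The lack of calls thus gives no check on the calls above.

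**Figure D3:**
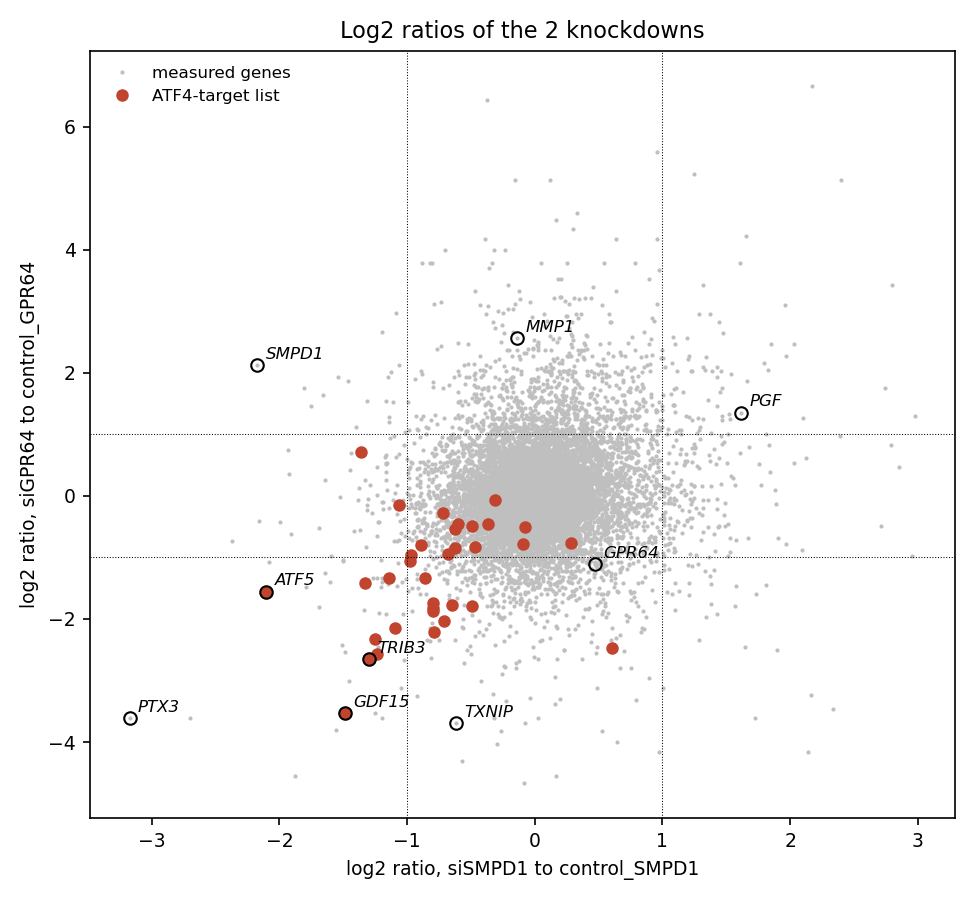
Log2 ratio of siSMPD1 to control_SMPD1 (x axis) against log2 ratio of siGPR64 to control_GPR64 (y axis) for 12386 genes, with the 34 ATF4 targets as filled points, dotted lines at 2-fold, and genes at 0 counts in a library drawn at their fitted ratio. Of the ATF4 targets 31 lie below 0 on both axes, and Pearson's r over all genes is 0.135.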

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

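All tests in this part were chosen after the data were first examined, and only the one on GC content and transcript length had its prediction written before its result was seen. The median log2 ratio of interferon-stimulated genes was -0.183 in siSMPD1 and 0.453 in siGPR64, each against its paired control, which gives the 2 comparisons opposite signs. Against the other control the signs were exchanged, with medians of 0.905 and -0.796. The difference between the knockdowns was not tested.

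The first pattern weighed was the number of genes past the rule of size in siGPR64, 1506. In 20 simulations without change at the depths of the GPR64 pair the highest number was 106, so counting error alone does not account for it. After the ratios were centred over GC content and length, 89.0% of the 1452 genes with known values stayed past the rule, so neither bias accounts for most of it. In siGPR64, 66.1% of the genes lay within 2-fold of control_SMPD1, while 47.1% did in control_GPR64, which is consistent with control_GPR64 standing apart from the other libraries. With 1 library per group, this could not be separated from an effect of the knockdown, which may also have moved genes toward control_SMPD1.

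The second pattern was the lower level of ATF4 targets in both knockdowns. Raised ATF4 targets in control_GPR64 alone do not account for it as a whole, since the median in siSMPD1 was -0.79 (random range -0.134 to 0.066) against control_SMPD1. For siGPR64 the median was -0.521 against control_SMPD1 (random range -0.202 to 0.159), which argues against that explanation. Between the 2 controls the median was 0.76, outside a random range of -0.223 to 0.197 and larger in size than -0.521, so the spread between single cultures keeps it open for this pair. The pattern could thus come from the knockdowns or from the state of the cultures, and these libraries do not separate them.

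The third pattern was the low level of both SMPD1 and GPR64 transcripts in control_GPR64. As labelled, GPR64 had a log2 ratio of -1.112 (-1.422 to -0.814) in siGPR64, the sign its siRNA would give, but the controls differed by -1.84 for this gene, so exchanged labels within the GPR64 pair stay open. Values that argue against siRNA against SMPD1 in control_GPR64 were GPR64 at 1.39-fold higher in siSMPD1, ATF4 targets at -0.79 in siSMPD1 but 0.76 in control_GPR64, and 41.3% (36.3% to 46.4%, genes taken as independent) of 385 genes past the rule in siSMPD1 that moved the opposite way in the GPR64 pair. Each culture is single and these genes are not independent, so this explanation is not excluded. No biological explanation was tested.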

How the results depend on the processing

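No paired analysis was possible for either knockdown alone because each group held 1 library, and the effect shared by both was tested with pair and knockdown terms. Depth limits the GPR64 pair, where a count of 0 allows up to 1.04 and 1.18 CPM, against 0.15 and 0.16 CPM in the SMPD1 pair. Of 152 alternatives for the counts, targets, list totals and overlaps, 101 stayed within 1.5 times the value given or, for targets, inside its counting interval. Some of these could hardly move. Correlations do not depend on the fold threshold, and neither correlations nor list totals respond much to scaling. The 43 genes higher and 29 lower in both with the controls exchanged count as kept, though each number was below that expected. A named gene was taken as kept if its value stayed inside its counting interval, as reversed if it was past the rule and changed sign, and otherwise as moved. A list was taken as kept if it stayed outside its random range on the same side, whatever the size. DESeq2 factors kept all 218 named-gene results and all 26 list results, total counts kept 217 and 26, and a prior of 5 counts kept 214 and 26. The numbers for scaling are not a check of the lists. Another scaling shifts all ratios of a comparison alike, in lists and random lists, so a list could hardly move. DESeq2 factors also lay close to the TMM factors, so named genes could hardly move either. A filter of 5 CPM kept 25 of the 26 lists and not ER chaperones in siGPR64, with a median of 0.218. The other control kept 70 named-gene results, moved 112 and reversed 36, and kept 12 lists, moved 6 and reversed 8. Of named genes short of the rule, 8 in siSMPD1 and 2 in siGPR64 also changed sign. Pooled controls gave 289 higher and 208 lower genes in siSMPD1 and 639 and 608 in siGPR64. The model of pair and knockdown, thinning, centring over GC content and length, and counts of 0 set to 3 were added after the data were seen. Counts of 0 set to 3 changed the lower genes of siGPR64 from 664 to 653 and those between the controls from 1066 to 1065, and no other count of the paired comparisons. Thinned to the depth of the GPR64 pair, siSMPD1 had 293 higher and 184 lower genes. Centred ratios gave 255 and 132 genes in siSMPD1, 776 and 618 in siGPR64 and 799 and 1030 between the controls.

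The counts of genes moved as follows, and unless the construction of the alternative explains it, the cause was not tested. A 1.5-fold threshold, which by construction admits more genes, gave 925 higher and 610 lower in siSMPD1, 1694 and 1454 in siGPR64, and 1864 and 2121 between the controls. A 3-fold threshold, which admits fewer, gave 61 and 26, 410 and 256, and 471 and 513. A filter of 5 CPM, which leaves fewer genes, gave 121 higher and 77 lower in siSMPD1 and 555 higher between the controls. No filter, which adds genes, gave 228 lower in siSMPD1. The other control gave 1356 higher and 1034 lower in siSMPD1. With the 2 controls as replicates, edgeR called 0 higher and 0 lower genes in each knockdown, beside 179 and 313 genes at an unadjusted p under 0.05. DESeq2 called 0 higher and 1 lower in siSMPD1 and 0 and 0 in siGPR64, beside 179 and 211 at an unadjusted p under 0.05. Both put the gap between the controls into the spread.

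Shared genes under 5 CPM, 1.5-fold and 3-fold, whose construction changes the number of genes, numbered 23, 185 and 11 higher in both, 21, 145 and 4 lower in both, and 11, 157 and 8 opposite. With no filter Pearson's r was 0.065, and the cause was not tested. With pair and knockdown terms edgeR called 1 gene higher and 4 lower and DESeq2 2 and 9, beside 864 and 456 at an unadjusted p under 0.05. With the controls exchanged in that model both called 0, beside 119 and 119. The gap between the controls then enters the spread of the model, so this does not check its calls. With the controls exchanged, 43 were higher in both, against 76.7 expected for independent lists, and 29 lower in both, against 49.2. Another 526 were opposite, against 124.3, and Pearson's r was -0.395 and Spearman's rho -0.340. This is partly by construction, since the gap between the controls then enters with opposite signs.

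Against the other control, targeted genes had log2 ratios of -2.950 (GPR64) and -0.837 (SMPD1) in siGPR64 and 2.311 (GPR64) and 0.798 (SMPD1) in siSMPD1. The lists outside their random range were 12 above and 7 below in siSMPD1 and 7 above and 7 below in siGPR64. List medians that reversed were 0.905 for interferon genes in siSMPD1 and, in siGPR64, -0.278 for EWS-FLI1-repressed targets, -0.160 for invasion genes, -0.427 for ER chaperones, -0.796 for interferon genes, -0.004 for G1/S genes, 0.378 for ribosomal proteins and -0.190 for YAP/TEAD targets. The medians of EWS-FLI1-repressed, invasion, G1/S and YAP/TEAD genes lay inside their random ranges there, so no reversal is shown for them. By construction, a gene's ratio to the other control is its paired ratio shifted by the gap between the controls. The cause of that gap was not tested.

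Named genes past the rule that reversed in siSMPD1 against the other control were ALDH1L2 (0.391), CDKN1A (-1.039), CXCL10 (1.509), CXCL11 (3.356), ITGA4 (-0.886) and LAMA5 (-0.430). In siGPR64 they were AMOTL1 (-0.314), CD68 (-0.530), CDKN1A (0.517), COL1A2 (-0.493), E2F8 (-0.539), EGR1 (0.902), FBN2 (4.427), FLT1 (-1.189), FOXO3 (0.705), GDF15 (0.95), HMMR (0.363), IFIT3 (-0.520), INSIG1 (-0.443), ITGA1 (-0.896), KRT8 (-0.127), LPHN2 (0.888), MMP1 (-1.921), MMP10 (-0.391), MMP9 (-1.613), NDRG1 (-1.120), NEAT1 (-0.382), NEFL (-0.965), NFKB1 (0.915), NT5E (-0.278), PAX7 (-0.641), PLAU (-0.203), PSMB8 (-0.943), TAGLN (-0.020), TAP1 (-1.455) and TNFRSF10A (-0.606). The counting interval against the other control included 0, so that no reversal is shown, for CXCL10 and CXCL11 in siSMPD1 and for CD68, KRT8, LPHN2, MMP10, NT5E, PLAU and TAGLN in siGPR64. The remaining reversals follow from the gap between the controls, whose cause was not tested.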

Other observations

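The genes in this part were chosen after their values were seen. TXNIP and its paralog ARRDC4, both targets of the glucose-sensing factor MondoA, set control_GPR64 apart from the other 3 libraries. TXNIP stood at 64.3 CPM in control_SMPD1, 42.0 CPM in siSMPD1, 372 CPM in control_GPR64 and 28.6 CPM in siGPR64. ARRDC4 stood at 5.83, 2.81, 63.0 and 7.05 CPM in the same order. The log2 ratio between the controls was 2.53 for TXNIP and 3.42 for ARRDC4. HSPA8 ran the other way, at 2778 CPM in control_SMPD1, 2414 CPM in siSMPD1, 549 CPM in control_GPR64 and 2859 CPM in siGPR64.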
